A study of Homo sapiens with 2 samples.

How the data were processed

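HepG2 cells were grown in medium with 25 mM glucose and 10% serum, per the labels' protocols. Crosslinked chromatin was sonicated and precipitated with a rabbit polyclonal antibody raised against residues 26 to 822 of recombinant human LSD2, per the labels. Libraries were size-selected for fragments of 100 to 250 bp, amplified for 15 cycles and had final lengths of 170 to 220 bp, per the labels' protocols. Sequencing used the Ion PGM and Ion Proton semiconductor instruments, and whether reads of both were pooled is not given in the sources used here. The 2 libraries were LSD2 ChIP (1 library) and input (1 library), and the group of each was taken from its source name. The ChIP and input read sets in the file header carry different run dates, so ChIP and input cannot be told apart from run in these data.

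The submitters' processing notes name BWA and the hg19 genome build. Per the file headers, the authors trimmed the reads, removed duplicate reads and called peaks with MACS for LSD2 against input. The settings, per the file headers, were a read length and an average fragment length of 120 bp, an effective genome size of 2700 Mb, a p-value cutoff of 1e-05, an enrichment factor of 32 and detection of local biases. Tool versions are not given in the sources used here. The deposited values are peak start and end positions, in bases, and no score, height or p per peak is given, so peaks could not be ranked by strength. A cutoff of this kind calls a region more readily where more reads fall, so peak number and peak width both move with sequencing depth and with the amount of DNA from a region. The depth of either library is unknown here, and no interval on read counts was computed. Starts were taken to count from 0, as the BED format defines, and positions are given counted from 1.

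Identical lines were counted as 1 peak. The 414095 lines gave 370863 distinct intervals, of which 37633 (10.1%) were listed more than once. Neighbouring intervals were treated as separate even where they touched, as 21 did with the next. The searched sequence of a chromosome ran from its first to its last peak, without the 32 peak-free stretches over 500 kb, and came to 2862 Mb. It took the place of the planned non-gap genome, since no genome sequence was used here, and so it can exclude sequence that was mappable but held no peak. It can also include stretches of up to 500 kb in which no peak could be called. Placed peaks can fall in such stretches, which spaces them more widely than the real ones. Random placements drew midpoints uniformly from this sequence and let placed peaks overlap. Peaks per chromosome were compared with 1000 placements over all chromosomes, two-sided, with Benjamini-Hochberg adjustment over the 24 chromosomes. Intervals for the density of a chromosome came from 1000 resamplings of its 5 Mb windows, and 10000 permutations of 5 Mb windows among chromosomes gave a second test. Clusters were 1 Mb windows above the highest, or below the lowest, window of their chromosome in 1000 placements within the chromosome. Spacing and runs were compared with 100 placements. Intervals on shares are Wilson 95% intervals and cover counting only. They treat peaks as independent, which neighbouring peaks are not.

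The tests of chromosomes, clusters, gene lists, base composition and motifs were fixed before the data were examined, as was the rule for what the text names. That rule names the 10 highest-scoring peaks by position where no annotation of the build is at hand, and peak width took the place of the score as the rule provides. The definition of runs, the position of the step on chromosome 14, the relation of width to density, the comparison with long peak-free stretches, the permutation of 5 Mb windows, the densest and sparsest windows named by position and the treatment of repeated lines were chosen after the positions had been seen. For clusters the plan named only windows above the placements, and the count of windows below them was added to it. The planned stricter thresholds by caller score were run on width instead, with 185432 peaks of at least 173 bp and 37086 peaks of at least 387 bp. Annotation classes, positions along gene bodies, occupancy of the fixed gene lists, base composition, motif content and the relation of score to location were not run. The only gene table used here is on the GRCh38.p14 assembly, and coordinates were not converted between builds. The planned genes are therefore not placed on the peaks.

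The procedures for chromosomes, clusters and runs were tested on simulated data. With chromosome X simulated at 0.5 times the density of the others, a ratio of 0.50 was recovered. Of 20 windows of 1 Mb simulated at 2-fold density, 20 were recovered, with 0 others called above among 2911 windows. Of 20 simulated runs, 20 were recovered. The simulated background was itself placed uniformly, as in the placements tested against. The simulations therefore show that what was put in is found, and not how often real uneven sequence is called wrongly. The simulated runs also held more peaks than most of the observed runs. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.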

Results

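Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to ask where LSD2 meets DNA in HepG2 cells grown under standard conditions. LSD2, encoded by KDM1B, is a flavin-dependent lysine demethylase that acts on methylated histone H3. HepG2 is an aneuploid human line derived from a liver tumour and is widely used as a model of hepatocytes. The data comprised 1 LSD2 ChIP library and 1 input library, the input being sonicated chromatin DNA that was not immunoprecipitated. Each condition had 1 library, so no difference in binding could be set against replicate error, and the tests below compare the peak list with random placements of the same peaks in the genome. The deposited result was a list of regions where LSD2 ChIP exceeded input. It gave positions only, without a height, fold enrichment or p-value per peak, and the sequencing depth of the libraries is unknown here.

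The deposited LSD2 peaks were numerous, mostly short and spread over all 24 chromosomes. The list held 414095 lines that described 370863 distinct intervals, none of which overlapped another. These intervals covered 86.9 Mb, which equals 3.22% of the 2700 Mb effective genome size that the authors gave to the peak caller. The median peak was 173 bp wide (95% interval of the median 172 to 173 bp), with a mean of 234 ± 120 bp (SD over peaks). Peaks from 140 bp to below 170 bp made up 47.3% of the set, and those from 200 bp to below 400 bp made up 34.3%. Within the broader class the number of peaks per 10 bp bin was nearly constant, at 6877 in the bin from 200 bp and 6071 in the bin from 390 bp. It then fell to 2410 in the bin from 410 bp. Only 371 peaks, or 0.100%, reached 1000 bp.

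**Figure D1:**
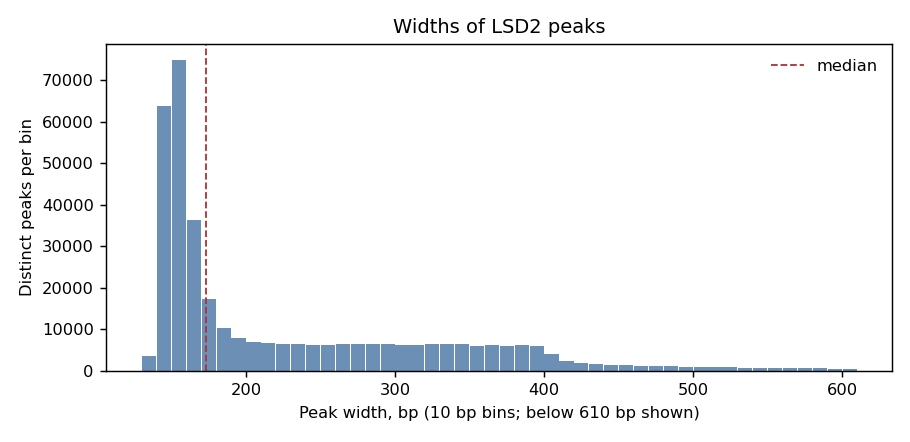
Number of distinct LSD2 peaks per 10 bp bin of peak width (bp), for widths below 610 bp, with the median of 173 bp as a dashed line. A narrow class near 150 bp is followed by a flat shoulder that ends near 400 bp.

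Peaks lay closer together than when placed at random over the searched sequence, and 46 runs of tightly spaced peaks stood out. The gap to the next peak had a median of 4218 bp (95% interval 4197 to 4241 bp), against 4970 bp, the mean of the medians, when peaks were placed at random within their chromosomes. Gaps under 1 kb made up 17.4% of all gaps (95% Wilson interval 17.3% to 17.5%), compared with 15.3% in those placements and 16.3% when peaks were placed at random within their own 1 Mb window. The observed share was above each of 100 placements of either kind (permutation test, one-sided p = 0.0099, the smallest that 100 placements can give). The excess over placements within the chromosome was 1.14 times, and 1.07 times over placements within the window. Placed peaks could fall in sequence where no peak can be called, which also gives such an excess. The comparison therefore does not separate clustering of LSD2 from uneven mappability.

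A run was counted where 15 or more successive peaks were each within 2 kb of the next. The 46 runs held 898 peaks on 17 chromosomes, whereas no placement of either kind gave more than 1 run. The longest placed run had 15 peaks when placed within the chromosome and 23 when placed within the 1 Mb window, so 3 of the observed runs, those of 30 or more peaks, were longer than any placed run. The longest lay on chromosome 2 from 216222491 to 216289420 (hg19), where 57 peaks with a median width of 508 bp covered 48.5% of 66.9 kb. A second run on chromosome 2, from 44168309 to 44212604, held 48 peaks over 44.3 kb with a median width of 354 bp. The third, on chromosome 20 from 47673101 to 47702125, held 30 peaks over 29.0 kb. Runs of 23 peaks were found on chromosome 10 from 113918545 to 113940631, on chromosome 11 from 9425777 to 9445237 and on chromosome 16 from 18871259 to 18896972. A run on chromosome 4 from 74299932 to 74324476 held 22 peaks and one on chromosome 13 from 98634305 to 98653175 held 21. Chromosome X, which had few peaks for its length, had 1 run, of 20 peaks from 133097485 to 133118819. Chromosome 2 had 8 of the runs, and chromosomes 4, 10 and 16 had 4 each. Peaks inside runs were wider than those outside, with medians of 349 and 172 bp, and the median of each of the 46 runs was above that of the peaks outside. The number of runs depended on the spacing allowed within a run, with 1 run at 1 kb and 184 at 3 kb. It also depended on the peaks used, with 16 runs among peaks of at least 173 bp, a set with fewer peaks. The rule for a run was chosen after the positions had been seen, and the placements spread peaks evenly within each 1 Mb window at most. The excess of runs therefore does not separate clustering of LSD2 from uneven mappability or from the amount of DNA from a region.

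Density differed between chromosomes, with the most peaks per Mb on chromosomes 2, 6 and 10 and the fewest on chromosomes 19, X and Y. Over all searched sequence there were 130 peaks per Mb. Chromosome 2 had 177 peaks per Mb (95% interval 168 to 185, from resampling its 49 windows of 5 Mb) and held 1.36 times the number that random placement gave. Chromosome 6 had 168 peaks per Mb (158 to 178), or 1.30 times the placed number, and chromosome 10 had 152 (139 to 162), or 1.17 times. Chromosome 19 had 88.0 peaks per Mb (81.0 to 93.7), the lowest of the 22 autosomes, at 0.68 times the placed number. Chromosome X had 64.0 (59.2 to 69.4), which was 0.513 times the autosomal median of 125 peaks per Mb. Chromosome Y had 42.7 (37.4 to 53.7). Peak number moves with the amount of DNA from a region, and the copy number of the chromosomes was not measured here. The searched sequence can also include sequence in which no peak could be called, which lowers the density of a chromosome, and mappability was not analysed here. These densities therefore do not separate copy number or uneven mappability from LSD2 binding.

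Against placements of single peaks, 6 chromosomes (2, 3, 6, 10, 17 and 20) were above and 15 were below the placed number, while chromosomes 4, 12 and 16 did not pass (permutation test, two-sided, adjusted p under the threshold of 0.05). For chromosomes 2, 6, 10, 19, X and Y the adjusted p of this permutation test was 0.0012, with an unadjusted 0.001 as the smallest that 1000 placements can give. Neighbouring regions are alike, so the chromosomes were also tested by permuting whole 5 Mb windows among chromosomes. Then 3 chromosomes were above (2, 6 and 10, with permutation adjusted p = 0.00048, 0.00048 and 0.018) and 5 were below. The 5 were chromosomes 9 and 14 (permutation adjusted p = 0.036 for both) and 19, X and Y (permutation adjusted p = 0.00048 for each), whereas 13 of the 21 chromosomes called before no longer passed, among them 3, 17 and 20. Counts of 1 Mb windows 5 Mb apart, with chromosome means removed, still correlated (r = 0.23, against at most 0.05 in 200 shuffles). Without chromosome 14 this correlation was 0.17, also against at most 0.05. Windows of 5 Mb are thus not independent, so the p-values of this second test can be too small and the intervals on density too narrow. Chromosome 14 had 109 peaks per Mb with a wide interval of 79.7 to 142, which includes the 130 peaks per Mb over all searched sequence. Among peaks of at least 387 bp, chromosome 14 held 1.03 times the placed number (permutation adjusted p = 0.27).

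**Figure D2:**
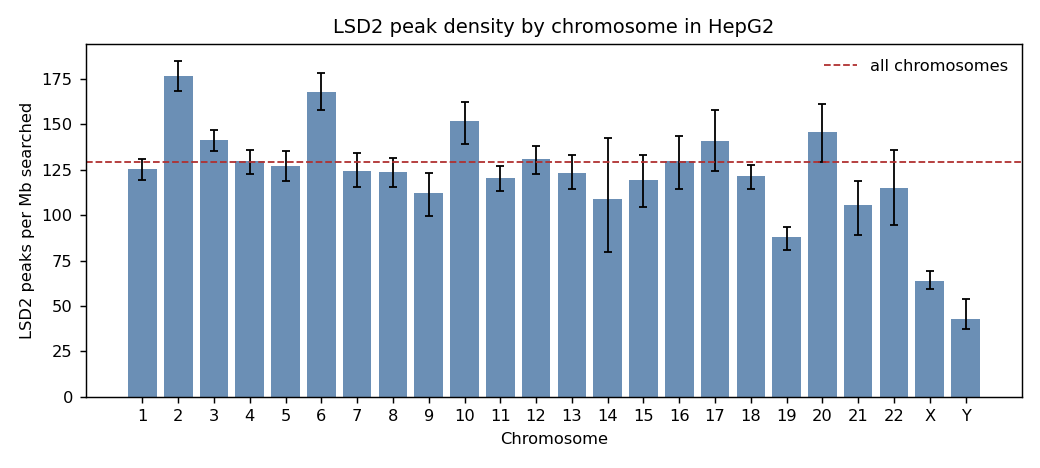
LSD2 peaks per Mb of searched sequence on each chromosome, with 95% intervals from resampling 5 Mb windows and the density over all chromosomes (130 peaks per Mb) as a dashed line. Chromosomes 2, 3, 6 and 10 lie above the line with their intervals. Chromosomes 9, 11, 18, 19, 21, X and Y lie below it with theirs, with 19, X and Y farthest. Of these, chromosomes 3, 11, 18 and 21 did not pass the permutation of 5 Mb windows.

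Along chromosomes, the clearest change was on chromosome 14, where peak density fell 3.23 times (95% interval 2.90 to 3.61) at 44 Mb. The 24 windows of 1 Mb before this position held 220 ± 42.2 peaks (SD over windows), and the 63 windows after it held 68.0 ± 20.9. The ranges did not overlap, at 119 to 322 before and 22 to 117 after. The last window before the step had 222 peaks and the first after it had 69. Peaks before the step were also wider, with a median of 216 bp against 161 bp. The step was located by choosing the division that fitted the window counts best, with at least 10 Mb on each side. The same procedure on the other 22 chromosomes with enough windows gave ratios of 1.11 to 1.70. The interval on the fall takes no account of the choice of the division. Its width is that of independent 1 Mb windows, which neighbouring windows are not, so it is too narrow. The ratio on chromosome 14 was 5.13 among peaks of at least 173 bp and 12.1 among those of at least 387 bp, and DNA copy number was not measured here.

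Across the genome, 249 of 2911 windows of 1 Mb held more peaks than any window of the same chromosome in 1000 placements. A further 248 of the 2807 windows searched over their whole length held fewer than any such window. Among peaks of at least 387 bp, a set with fewer peaks, these numbers were 107 and 18. Chromosome 14 contributed 22 of the dense windows and 34 of the sparse ones, chromosome 2 contributed 23 and 19, and chromosome X contributed 7 and 2. The typical window had 130 ± 46.7 peaks (SD over windows). The densest was chromosome 2 from 216000001 to 217000000, with 333 peaks, against a highest placed window of 236 on that chromosome. The run at 216222491 accounted for 17.1% of its peaks. Chromosome 14 from 31000001 to 32000000 followed with 322 peaks of 340 bp median width, and chromosome 6 from 119000001 to 120000000 with 297. Chromosome 2 had further windows at 290 peaks (from 55000001), 283 (from 44000001), 277 (from 54000001) and 274 (from 178000001). A window on chromosome 6 from 126000001 also held 274 peaks. The windows from 17000001 on chromosome 8 and from 30000001 on chromosome 3 held 273 and 272.

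**Figure D3:**
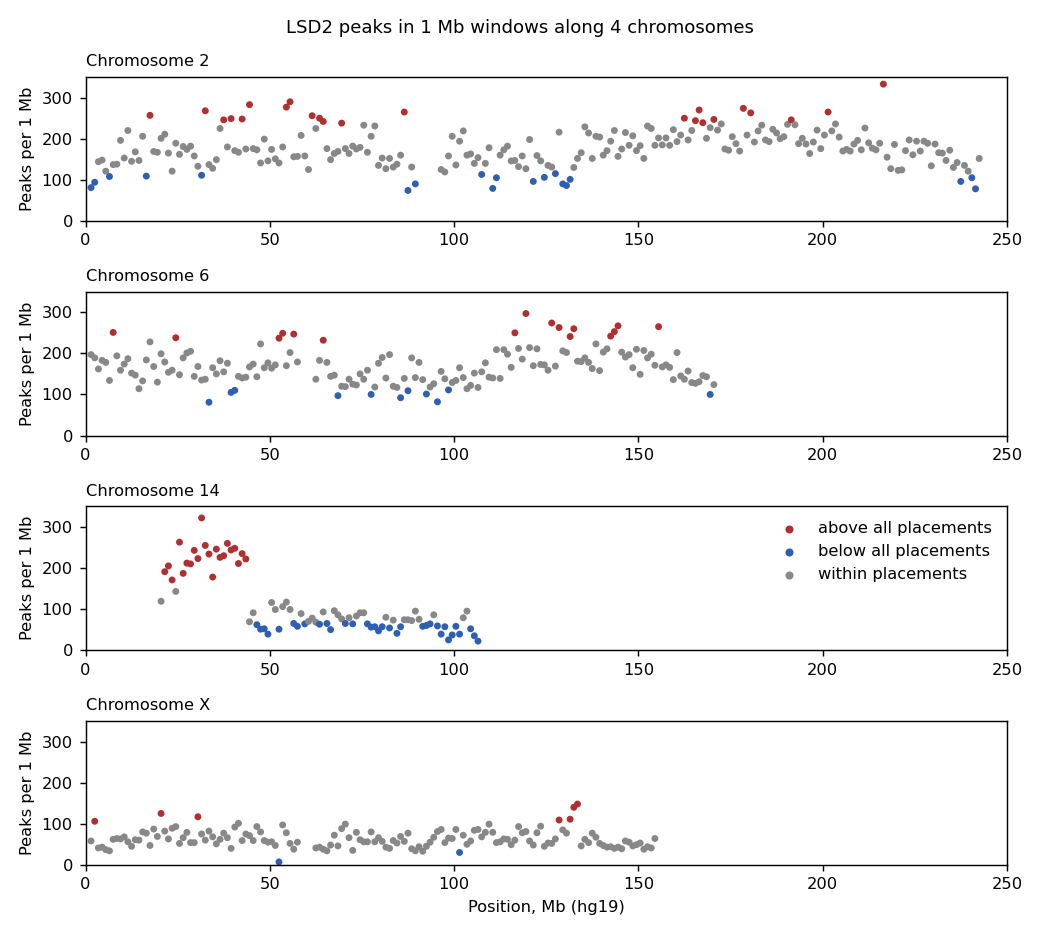
LSD2 peaks per 1 Mb window along chromosomes 2, 6, 14 and X (position in Mb, hg19), for windows searched over their whole length, coloured by whether the count was above, below or within that of 1000 placements on the same chromosome. Chromosome 14 falls from a mean of 220 to 68.0 peaks per window at 44 Mb.

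At a finer scale the densest 100 kb was chromosome 2 from 216200001 to 216300000, with 74 peaks of 465 bp median width. Chromosome 9 from 95000001 to 95100000 held 69 peaks, chromosome 2 from 44100001 to 44200000 held 65, chromosome 16 from 18800001 to 18900000 held 63 and chromosome 11 from 9400001 to 9500000 held 59. Sparse windows were found on chromosome X from 52000001 to 53000000, with 7 peaks, and on chromosome 5 from 69000001 to 70000000, with 10. Chromosome 9 had several, among them 11 peaks from 41000001 to 42000000 and 12 from 43000001 to 44000000. The lowest placed window was 32 on chromosome X, 73 on chromosome 5 and 71 on chromosome 9. Windows counted as searched can hold sequence where no peak could be called, and mappability was not analysed here. A low count in these windows therefore need not mean little LSD2.

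**Figure D4:**
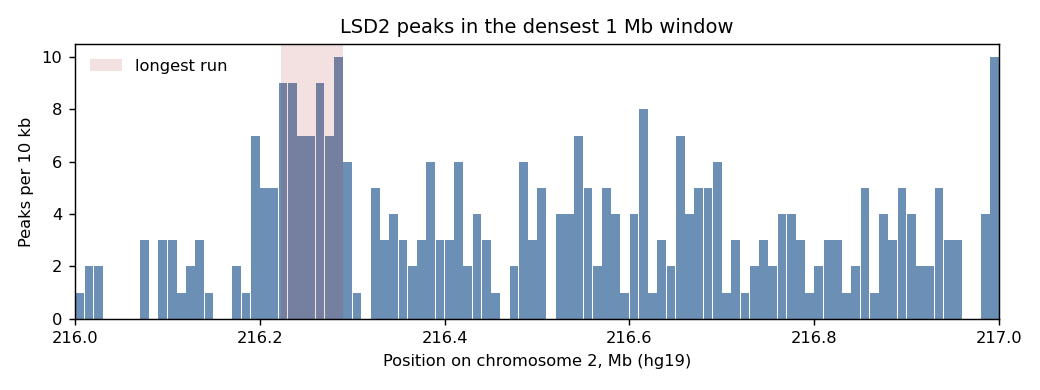
LSD2 peaks per 10 kb on chromosome 2 from 216 to 217 Mb (hg19), the 1 Mb window with the most peaks (333), with the run of 57 peaks shaded. Bins inside the run reach 10 peaks, as does the last bin of the window, against a median of 3 over the window.

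Windows with more peaks also had wider peaks. Spearman's rho between peak count and median width was 0.69 over 2806 windows of 1 Mb (circular-shift permutation test, two-sided p = 0.001, the smallest that 1000 shifts can give). Windows are not independent replicates. Peak number and peak width both move with the amount of DNA from a region, so the relation need not come from LSD2 binding. The relation was positive within each of the 24 chromosomes, from 0.35 on chromosome 19 to 0.79 on chromosome 20. Peaks in the 249 dense windows had a median width of 201 bp, against 170 bp elsewhere. By chromosome, median width ran from 161 bp on X to 187 bp on chromosome 2.

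Of the 10 widest peaks, 8 lay within 1 Mb of one of the 24 peak-free stretches longer than 1 Mb. The widest was 6959 bp on chromosome Y from 13479946 to 13486904, followed by 6658 bp on chromosome 1 from 121351637 to 121358294. Then came 5138 bp on chromosome 8 from 43092462 to 43097599, 4880 bp on chromosome 16 from 46425376 to 46430255, and 4521 bp on chromosome Y from 13465739 to 13470259. The rest of the 10 widest were on chromosome 16 (4035 bp from 33971962 and 3189 bp from 46422172), chromosome Y (3797 bp from 58982735), chromosome 9 (3060 bp from 68419630) and chromosome 21 (2639 bp from 10699040). Among the 371 peaks of 1000 bp or more, 12.7% lay that close to such a stretch, compared with 1.05% of the other peaks. This comparison was chosen after the widest peaks had been seen, and wide peaks can neighbour one another, so no test is given.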

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

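The stricter sets for peak number, width, spacing, chromosomes and clusters, the merging of peaks and the 250 kb windows for clusters were planned, and the other alternatives were chosen after seeing the data. Counting every deposited line gave 414095 peaks, and merging peaks up to 100 bp apart gave 368304, against 370863. The stricter set of peaks of at least 173 bp holds, by construction, 185432 peaks with a median of 298 bp. Gaps under 1 kb were 16.8% after merging, which removes the shortest gaps, and 11.4% in the set of at least 173 bp, which has fewer peaks. Of 48 values for the 8 chromosomes followed across alternatives (2, 6, 10, 14, 19, 20, X and Y), 46 kept their direction and side of the threshold. Chromosome 14 turned from 0.84 to 1.03 times the placed number among peaks of at least 387 bp (permutation adjusted p = 0.27, range over its alternatives 0.001 to 0.27), and its density ratio rose from 3.23 to 12.1 there and to 5.13 among peaks of at least 173 bp, and the cause was not tested. Over all chromosomes, permuting 5 Mb windows kept 8 of 21 calls, with 3 above in place of 6 and 5 below in place of 15, and among the 13 lost was chromosome 20 (permutation adjusted p = 0.33, range 0.001 to 0.33). Dense windows numbered 107 and sparse ones 18 among peaks of at least 387 bp, a set with fewer peaks, and 89 of the 107 were among the original 249. The other alternatives gave 218 to 360 dense windows. Among these, the 316 dense windows of 250 kb were out of 11499 windows, against 249 of 2911 windows of 1 Mb, so a smaller share was called. Runs numbered 1 with gaps up to 1 kb, 184 with gaps up to 3 kb and 16 among peaks of at least 173 bp, against 46. Width and density had rho = 0.48 in 250 kb windows and 0.68 without chromosome 14. The alternatives for annotation classes, gene bodies, gene lists, base composition, motifs and score by location were not run, since those results were not. No paired analysis was possible because each group had 1 library. The unknown depth limits every count, since the list cannot separate a region without LSD2 from one with too few reads to pass the cutoff.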

Other observations

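The tests of long segments and of repeated lines against gene density were chosen before their results were seen, and the other tests here after the patterns had been seen. Regional differences were found on chromosomes other than 14, with smaller ratios. On chromosome 15 the 12 windows of 1 Mb before 34 Mb held 75.3 ± 13.8 peaks (SD over windows), against 128 ± 34.8 in the 68 after it. On chromosome 17 the 21 windows before 26 Mb held 109 ± 23.1 peaks and the 55 after it held 154 ± 47.2. Chromosome 6 had 157 ± 36.8 peaks per window before 111 Mb and 189 ± 42.6 after. The last 10 windows of chromosome 10 held 96.3 ± 30.1 peaks, against 158 ± 42.1 before them, and the last 10 of chromosome 12 held 85.8 ± 39.6, against 135 ± 33.0. On chromosome 4 the first 11 windows held 84.1 ± 24.4 peaks, against 133 ± 29.1 in the rest. These positions were chosen to part the counts best, which inflates the differences. On chromosomes 10 and 12 the division lay at the limit of 10 Mb that the procedure allowed, so the limit may have set it. Across the division on chromosome 12 the count rose, from 133 peaks in the last window before it to 183 in the first after. A hypothesis of density changing over long chromosome segments was tested by correlating counts of windows 10 Mb apart, with chromosome means removed. The correlation was 0.12 over 2471 pairs, against at most 0.07 in 200 shuffles, and for windows 20 Mb apart it was 0.02, against at most 0.05. Without chromosome 14 the value at 10 Mb was 0.06, against at most 0.05, so its size rests largely on that chromosome, whereas for windows 1 Mb apart it was 0.43, and 0.37 without chromosome 14.

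The first pattern is the step on chromosome 14. The median gap between neighbouring peaks was 3.24 times as long after it, but this moves with the density (0.85 to 1.07 times the density ratio over the 23 chromosomes divided), so it decides nothing about less searchable sequence. Sequence lost in stretches much longer than a peak would remove peaks of every width alike, but the density ratio among peaks of at least 387 bp was 3.75 times that of all peaks (95% interval 2.93 to 4.68, from resampling the 5 blocks of up to 5 Mb before the step and the 14 after it), which argues against it. DNA copy number in this aneuploid line is a candidate explanation and would change density abruptly, but the ratio of the 5 windows on either side, 1.10 times that of the whole sides, does not decide, as 7 of the other 22 chromosomes gave a value as high at their own best division (range 0.70 to 1.41). Copy number, finely scattered unsearchable sequence and a regional difference in LSD2 binding cannot be told apart from peak positions alone. The input reads were not analysed here, and a regional difference in LSD2 binding was not tested.

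The second pattern is the repetition of lines, in which 33182 intervals were listed 2 times and 4451 intervals 3 or more times, up to 21. A separate line per sequencing platform allows at most 2 lines each, so the 4451 argue against it. A line per annotated gene at the peak is a candidate explanation that stays open: over 24 chromosomes, genes per Mb in the GRCh38.p14 table and the percent of intervals listed more than once had Spearman's rho = 0.76 (permutation test, p = 3e-05, adjusted over 2 relations 6e-05) and Pearson's r = 0.92 (permutation p = 1e-05, adjusted 2e-05), and r = 0.79 without the 2 chromosomes farthest from the median gene density. The 21-line intervals lie on chromosome 5 (in a group of 6 from 140792041 to 140870409, picked for having 9 or more lines, whose line number never falls along the chromosome), and the deepest overlap of named coding genes in the table is 22, the protocadherin genes from PCDHGA1 to PCDHGC5, also on chromosome 5. Line number also never falls in a group of 24 intervals on chromosome 5, from 140223626 to 140379365. It does fall in a group of 8 intervals on chromosome 2, from 234634204 to 234680800, of which 6 had exactly 9 lines. The deepest overlap of coding genes on chromosome 2 is also 9, the UGT1A genes. Since intervals were picked for having 9 or more lines and positions were not converted between builds, this likeness does not decide. On the 23 chromosomes other than chromosome 5 the most lines of an interval exceeded the deepest overlap of coding genes (11 against 9 on chromosome 2 and 11 against 3 on chromosome 11), and on 19 of the 24 it exceeded that of genes of any type, and the annotation behind the list is not given in the sources used here.

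The third pattern is the position of 8 of the 10 widest peaks within 1 Mb of long peak-free stretches. Repeats that are present in more copies in the cells than in the assembly, beside unassembled sequence such as centromeres, may pile up reads. The odds ratio of 13.7 for peaks of 1000 bp or more measures the pattern itself and is no separate support for this, and 324 of the 371 such peaks lay elsewhere. Sequence content was not analysed here, so the explanation stays open, and no biological explanation was tested.

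A further hypothesis, that gene-rich chromosomes hold more LSD2 peaks, was tested with no clear relation found in either direction. Over the 22 autosomes, coding genes per Mb and peaks per Mb had Spearman's rho = -0.22 (permutation test, p = 0.32, adjusted 0.32) and Pearson's r = -0.41 (permutation p = 0.072, adjusted 0.072), and r = -0.19 without the 2 chromosomes farthest from the median.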
